A study of Mus musculus with 4 samples.

How the data were processed

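Sperm DNA of C57/Bl6 mice was profiled by methylated DNA immunoprecipitation and sequencing (MeDIP-seq), in which an antibody against 5-methylcytosine pulls down fragments of denatured DNA and the recovered fragments are sequenced. Read density in a region therefore rises with the number of methylated cytosines a fragment carries, and it is not a methylation level. Per the labels' protocols, sperm came from the caudal epididymis of males of about 12 weeks, and 4 µg of DNA per immunoprecipitation was sheared to a mean of 300 bp. There were 4 libraries from 3 diets, with 1 library of caloric restriction, 2 of the control diet and 1 of a low protein diet. Sample titles also carry a code, B43 for caloric restriction 1 and control 1 and B87 for control 2 and low protein 1, and what the code stands for is not given in the sources used here. Whether the 2 control libraries came from different males or pools is likewise not given, so any spread between them may be technical.

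The deposited files hold 1 line per aligned read with its chromosome, start, end and strand, so the deposited unit is a read position (neither counts per feature nor a ratio, score or signal). Bowtie and the mouse build mm9 are named in the submitters' processing notes, with no version or alignment setting given there. All reads in the files spanned 30 bp, and the name and score columns held 1 value throughout. How reads that match several places were treated is not given in the sources used here. No input library was used here, so local copy number and mappability were not corrected.

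From these positions, reads were counted here in 5-kb windows along every chromosome. At most 1 read per position and strand was counted, and each 5′ end was moved 150 bp along its strand to stand for the middle of a 300 bp fragment. Windows with a mean of at least 10 reads over the 4 libraries entered the tests. Values were log2 CPM (reads of a window scaled to the library total) with a prior count of 0.5. Diets were compared with limma 3.58.1 in R 4.3.3, with a mean trend and Benjamini-Hochberg adjustment over all windows, in 1 fit of all 4 libraries. The 2 controls give the only residual degree of freedom (1 in all), so the single library of each diet was assumed to vary like the controls. In the main fit the prior degrees of freedom were estimated as infinite. The SD of each window was therefore taken from the mean trend alone. The SE given for a window does not reflect the spread of its own 2 control values. With the title code as a block, 0 residual degrees of freedom remain and no test exists, so ratios to the control of the same code are given as values. The choice of limma follows from the unit, since the files hold positions and the counts were made here.

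The fit was tested on simulated data for caloric restriction against control, with 200 of 428170 windows changed. With no difference between the codes it called 28 of 100 windows changed 2-fold and 77 of 100 changed 4-fold, but also 61 unchanged windows, so false calls exceeded the nominal rate. With each library drawn from the summed profile of its code, which keeps the difference between the codes, it called 0 of 100 and 41 of 100, and 1 unchanged window. These draws hold no difference between libraries of a code, so they leave out part of the difference between the controls. The power in the real data may therefore be lower. A minimum mean of 30 reads, with no difference between the codes, gave 46 of 100, 95 of 100 and 38 unchanged windows among 228602. At 66 windows with extreme read numbers the fitted SD was above 2 on the log2 scale, so the test had no power there.

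For comparisons between pairs of libraries, each library was thinned at random to the 15223868 reads of the smallest. Counting error was simulated by sharing the reads of each pair out at random between its libraries, window by window, in 5 draws. A first version shared the reads out over all 4 libraries and was replaced after its result was seen. The correlation between the ratios of the 2 diets was set beside 20 simulated draws without a diet difference. Intervals are 95% and exact (Poisson for a count, Clopper-Pearson for a ratio of 2 counts); they cover counting error only, since reads without molecular identifiers are not independent molecules. The distance between read starts on opposite strands was measured per autosome over lags of 40 to 600 bp, above the mean of lags from 500 bp; it replaced a first version on 1 chromosome.

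Windows named by position followed a rule fixed before the data were examined. For each diet they are the 10 windows with the largest increase and the 10 with the largest decrease in mean log2 ratio to the 2 controls, among windows with a mean of at least 20 reads, the same direction against both controls, and a smaller difference between the controls than between the diet and either control. Alternatives fixed at the same time were all reads, no shift, median-ratio size factors, cyclic loess, other filters, a prior count of 5, voom weights, autosomes without windows above 10 times the median, thinned libraries, other window sizes and a 1.5-fold limit. Analyses in 50-kb and 1-Mb windows, fits without a mean trend, the mitochondrial total, the distance between strands and the chromosome 17 window were chosen after the data were seen.

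Promoters, 13 gene lists and CpG density were planned but not analysed here, since they need the mm9 sequence and annotation, which were not used here. The gene table at hand is for another build, GRCm38, and coordinates were not converted, so regions are named by mm9 position and no gene is assigned to them. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.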

Results

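The study asked whether the diet of a male mouse changes cytosine methylation in its sperm. Sperm DNA of males on a control diet, under caloric restriction or on a low protein diet was enriched for 5-methylcytosine and sequenced. The libraries held 18046785 reads for caloric restriction 1, 15223868 for control 1, 28942004 for control 2 and 17180879 for low protein 1. Distinct positions numbered 16417987, 14071167, 25546248 and 16109533, in the same order, so that 9.03%, 7.57%, 11.7% and 6.24% of reads repeated a position already seen.

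Methylated DNA was recovered unevenly along the genome in all 4 libraries, and the main features of the landscape were shared. Chromosomes 11 and 19 had the highest median reads per 5-kb window. For chromosome 11 the median was 1.32 times that of the autosomes in caloric restriction 1, 1.42 times in control 1, 1.20 times in control 2 and 1.26 times in low protein 1. Chromosome 3 was the lowest autosome in all 4 libraries, at 0.800, 0.737, 0.841 and 0.815 times. The X chromosome lay far below the autosomes, at 0.240, 0.211, 0.273 and 0.259 times. A sperm carries either an X or a Y chromosome, but how far this accounts for the low values was not tested.

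**Figure D1:**
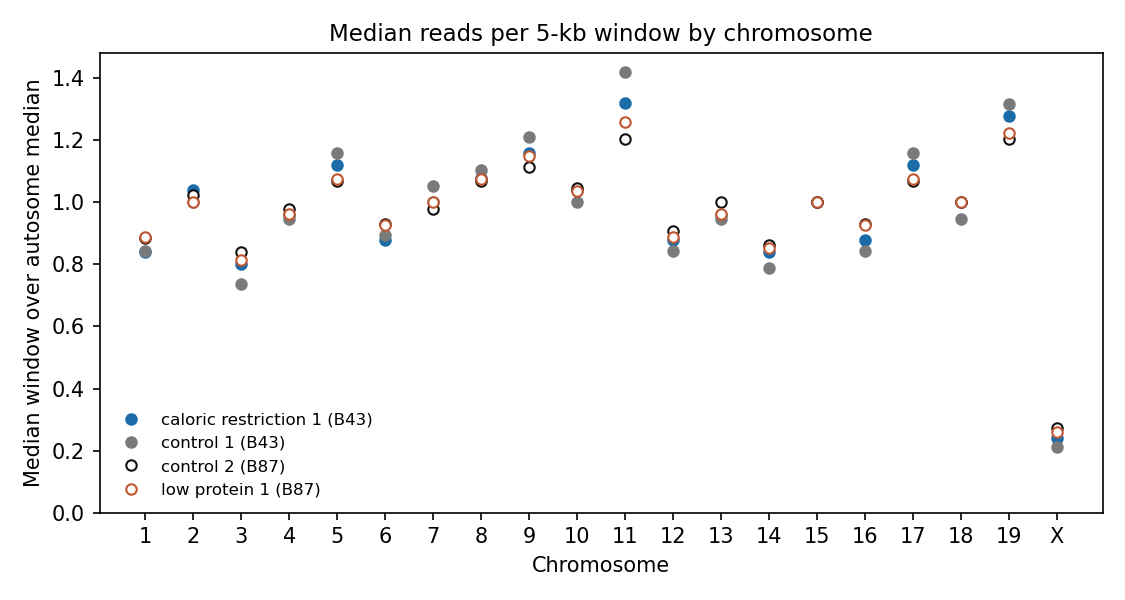
Median number of reads per 5-kb window on each autosome and the X chromosome, divided by the median over all autosomes (vertical axis, no unit), for each of the 4 libraries; filled points are libraries with title code B43 and open points those with B87. The X chromosome lies between 0.211 and 0.273, below every autosome.

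The 1-Mb regions compared were those of the autosomes with a mean of at least 2000 distinct reads over the 4 libraries. Among these, chromosome 5 from 114000001 to 115000000 had the highest mean CPM of distinct reads, although other regions were higher in each library. It held 1192 CPM in caloric restriction 1, 1513 in control 1, 897 in control 2 and 1007 in low protein 1, and the mean was 3.03 times the median region. Chromosome 4 from 140000001 to 141000000 followed, with a mean of 1145 CPM. Among the regions kept, the lowest mean was on chromosome 7 from 92000001 to 93000000, at 0.283 times the median region. It held 90.7, 75.9, 137.7 and 125.9 CPM, although in 3 of the libraries another region was lower. Regions with fewer reads were left out, so this low end was set by the limit of 2000. Regions of chromosome 3 from 91000001 to 92000000 and chromosome 17 from 38000001 to 39000000 were similar, at 0.291 and 0.292 times. The highest regions depended on repeated reads: when all reads were counted, chromosome 2 from 98000001 to 99000000 held the most, at 61.4 times the median region against 0.585 times with distinct reads.

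Libraries differed in how strongly reads were concentrated. The 10% of windows with the most reads held 31.2% of distinct positions in caloric restriction 1 and 35.8% in control 1, against 26.1% in control 2 and 27.5% in low protein 1. The 2 controls, which share a diet, were the extremes. The mean distance between read starts on opposite strands, which follows fragment length, was 126.9 bp ± 2.36 (SD over 19 autosomes) in caloric restriction 1 and 141.6 bp ± 3.58 in control 1. It was 178.8 bp ± 1.04 in control 2 and 164.0 bp ± 1.40 in low protein 1, so that the title codes did not overlap. All 4 values were below the stated mean of 300 bp.

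**Figure D2:**
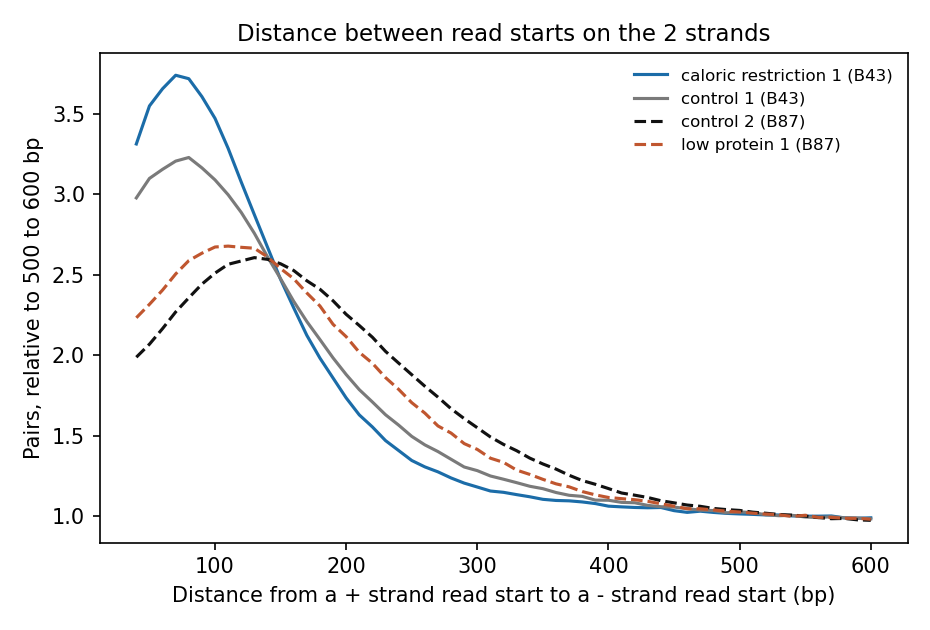
Number of pairs of read starts on opposite strands at each distance (horizontal axis, bp), relative to the mean at 500 to 600 bp (vertical axis), for each library; solid lines have title code B43 and dashed lines B87. The most frequent distance was 70 bp in caloric restriction 1, 80 bp in control 1, 130 bp in control 2 and 110 bp in low protein 1.

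Caloric restriction against control asks which regions of sperm DNA gain or lose methylation when food is limited. None of 428170 windows passed an adjusted p of 0.05 (limma, 1 caloric restriction and 2 control libraries), and the smallest adjusted p was 0.9999. At an unadjusted p under 0.05 there were 1055 windows, or 0.246%. Other settings on the same windows also called 0, with 1167 (voom weights) to 7126 (cyclic loess) at that level. Without any difference, p-values that hold their level would put a share of 0.05 of windows there. The test was thus conservative, and the absence of calls says little about the diet. The window with the largest increase by the naming rule was the start of the mitochondrial chromosome, positions 1 to 5000. It held 48 distinct reads in caloric restriction 1 against 9 in control 1, 31 in control 2 and 12 in low protein 1. Its mean log2 ratio to the controls was 1.70 (SE 0.69, limma). The whole mitochondrial chromosome held 116 distinct reads in caloric restriction 1 against 41 in control 1 and 59 in control 2. With no input library, a larger amount of mitochondrial DNA cannot be told from more methylation here. Chromosome 6 from 60840001 to 60845000 held 45 reads against 14 and 25 in the controls, a log2 ratio of 1.45 (SE 0.60). The X chromosome window from 133605001 to 133610000 held 47 reads against 15 and 30, a log2 ratio of 1.34 (SE 0.57).

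The windows with the largest decrease under caloric restriction had few reads in that library. Chromosome 8 from 84945001 to 84950000 held 4 reads against 11 in control 1 and 51 in control 2, a log2 ratio of -2.23 (SE 0.80) that was -1.58 against control 1 alone and -2.88 against control 2 alone. Chromosome 6 from 78460001 to 78465000 held 6 reads against 21 and 50, a log2 ratio of -2.13 (SE 0.66). None of these windows passed the adjusted threshold. Against the control of its own title code, caloric restriction 1 was at least 2-fold higher in 24627 windows and lower in 5151, with no test possible. That split depended on scaling: with median-ratio size factors, which moved the median log2 ratio from 0.08 to -0.05, it was 18164 higher and 8551 lower, and after loess on the mean log2 count it was 12785 higher and 11987 lower.

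Low protein against control asks the same of a diet poor in protein. None of 428170 windows passed an adjusted p of 0.05 (limma, 1 low protein and 2 control libraries), and the smallest adjusted p was 0.9999. At an unadjusted p under 0.05 there were 1025 windows, or 0.239%. Other settings on the same windows also called 0, with 1651 (voom weights) to 5817 (cyclic loess) at that level. These shares were again far below 0.05, so this test was conservative too, and the absence of calls says little about the diet. The largest increase was on chromosome 2 from 40105001 to 40110000, where low protein 1 held 43 distinct reads against 7 in control 1 and 28 in control 2. Its mean log2 ratio to the controls was 1.81 (SE 0.74, limma). Chromosome 11 from 14270001 to 14275000 held 39 reads against 8 and 21, a log2 ratio of 1.78 (SE 0.77). The largest decrease was on chromosome 9 from 69515001 to 69520000, with 9 reads against 26 and 55, a log2 ratio of -1.78 (SE 0.59). Chromosome 2 from 18520001 to 18525000 held 16 reads against 39 and 82, a log2 ratio of -1.56 (SE 0.44). None of these windows passed the adjusted threshold.

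When all reads were counted, 1 window was called lower in low protein 1. It lay on chromosome 10 from 62975001 to 62980000, with 18 reads against 141 and 128 in the controls (log2 ratio -2.58, adjusted p = 0.0177, limma). These reads fell on few distinct positions, 6 in low protein 1, 7 in control 1 and 10 in control 2. A 50-kb analysis chosen after the data were seen called 17 windows for caloric restriction and 11 for low protein with a minimum mean of 10 reads. These calls rested on means of 10 to 15.5 reads per library, where the fit used an SD of 0.0858 to 0.208, below the 0.366 to 0.456 that counting alone gives. With a minimum of 100 reads, a filter chosen after those calls were seen, 0 windows were called for either diet, and 0 also with a minimum of 10 reads and no mean trend.

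Pairs of libraries thinned to the same number of reads, of which 13935015 to 14329797 distinct positions were counted, show how large differences were with and without a change of diet. The 2 controls differed at least 2-fold in 14.5% of 387718 windows, against 3.03% from counting error alone. Low protein 1 and control 2 differed in 2.45%, against 2.28% from counting error. Caloric restriction 1 and control 1 differed in 5.94%, against 3.84%. Beyond counting error, the SD of the log2 ratio was 0.53 between the controls, 0.24 between caloric restriction 1 and control 1, and 0.09 between low protein 1 and control 2. Sharing a code did not always mean a smaller difference, since caloric restriction 1 and low protein 1, of different codes, differed in 4.97% of windows with an SD of 0.25 beyond counting error. With a minimum mean of 30 reads the controls differed in 6.36% of windows and low protein 1 and control 2 in 0.299%.

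**Figure D3:**
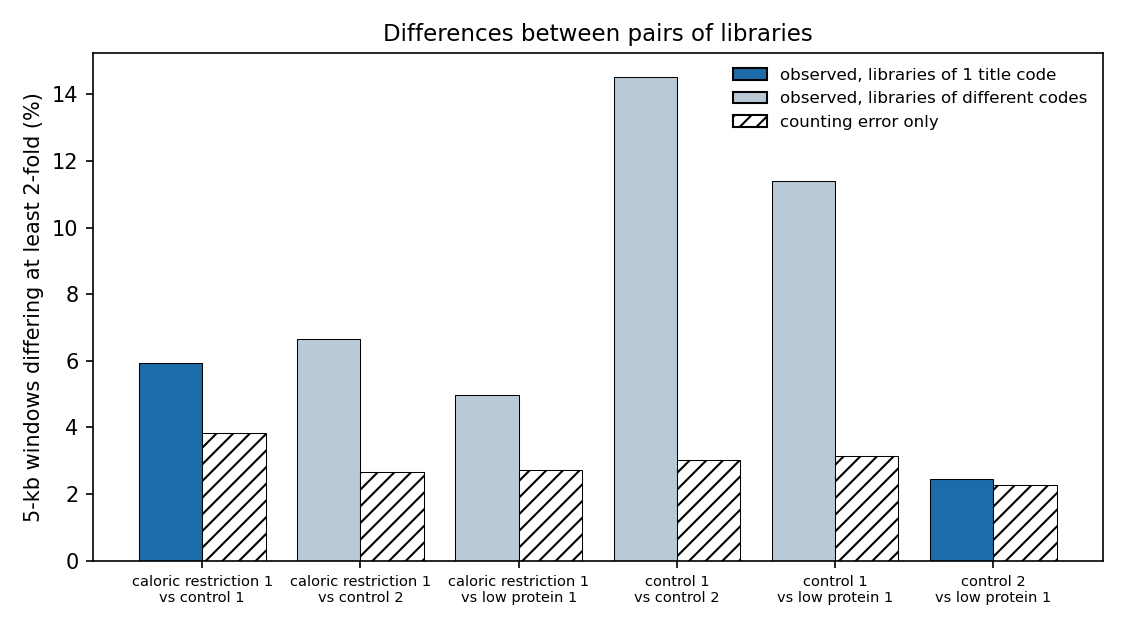
Percent of 5-kb windows that differed at least 2-fold between each pair of libraries thinned to equal numbers of reads (vertical axis, from 0); dark bars are pairs with the same title code, light bars pairs with different codes, and hatched bars the percent from counting error alone. The 2 controls stand highest at 14.5%, and control 2 with low protein 1 lowest at 2.45%.

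The difference between the controls followed read level. Over windows ranked by the other 2 libraries, the median log2 ratio of control 1 to control 2, centred on 0, went from -0.56 in the 10% with the fewest reads to 0.64 in the 10% with the most. The ratio of caloric restriction 1 to control 1 went from 0.14 to -0.22, and that of control 2 to low protein 1 from 0.08 to -0.12. In larger windows the order of these pairs was the same. Of 47075 windows of 50 kb with a mean of at least 100 reads, 24 differed at least 1.5-fold between low protein 1 and control 2. Caloric restriction 1 and control 1 differed so in 1679, and the controls in 15276. More reads per window lower the counting error, which was not simulated at 50 kb. These numbers therefore do not show whether a pair was closer than in 5-kb windows.

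**Figure D4:**
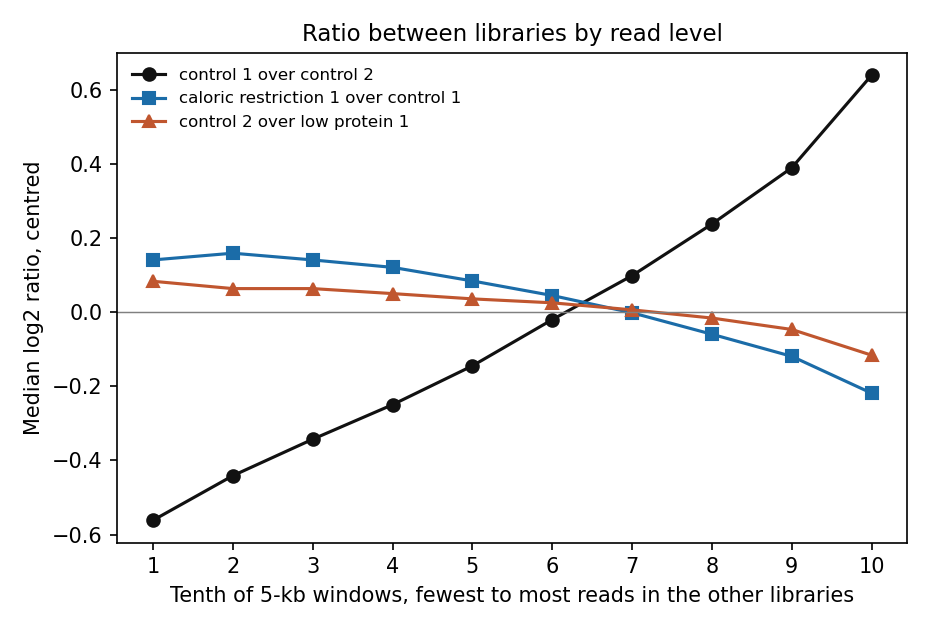
Median log2 ratio between 2 libraries, centred on 0 (vertical axis), in groups of 10% of 5-kb windows ranked by reads in the other 2 libraries (horizontal axis). Control 1 over control 2 rises from -0.56 to 0.64, while both ratios within a title code stay between -0.22 and 0.16.

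Whether the diets moved the same windows was asked from the ratios within a title code, which share no library. Across windows, which are not independent replicates, Pearson's r was -0.0914 (jackknife SE 0.00637 over chromosomes) and Spearman's rho -0.106, against simulated values from -0.00211 to 0.00313 without a diet difference. The simulated libraries of a code have the same expected values, so they lack the trends with read level that the ratios within a code have. The r depended on the setting: it was -0.0421 after loess on the mean log2 count, -0.154 with a minimum mean of 30 reads and -0.416 in 50-kb windows, chosen after the data were seen. The r was -0.444 with the controls crossed, where libraries drawn without a diet difference but with the code difference gave -0.471. Against the mean of both controls r was 0.224 and the covariance 0.0365, and in 50-kb windows the sign turned, with -0.0454 and -0.00123. Libraries drawn without a diet difference gave a covariance of 0.0396 from shared controls alone. With the code difference kept as well, the draws gave 0.00373, and the observed 5-kb value lies between these.

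A region of chromosome 17 differed widely between the libraries. Chromosome 17 from 39980001 to 39985000, singled out after its values were seen, held 720 CPM (all reads) in caloric restriction 1, 1105 in control 1, 164 in control 2 and 347 in low protein 1. Low protein 1 was 2.12-fold above control 2 (interval 2.04 to 2.20), control 1 was 1.53-fold above caloric restriction 1 (1.5 to 1.57), and control 1 was 6.75-fold above control 2 (6.54 to 6.98). With distinct positions, as in the main counting, these folds were 2.12 (2.01 to 2.24), 1.34 (1.29 to 1.39) and 4.24 (4.04 to 4.46). The next window, from 39985001 to 39990000, was higher in control 1 than in control 2 by 7.10-fold with all reads and 4.29-fold with distinct positions. The 50-kb window around both, from 39950001 to 40000000, was the only 1 of these 47075 at least 2-fold apart between low protein 1 and control 2.

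**Figure D5:**
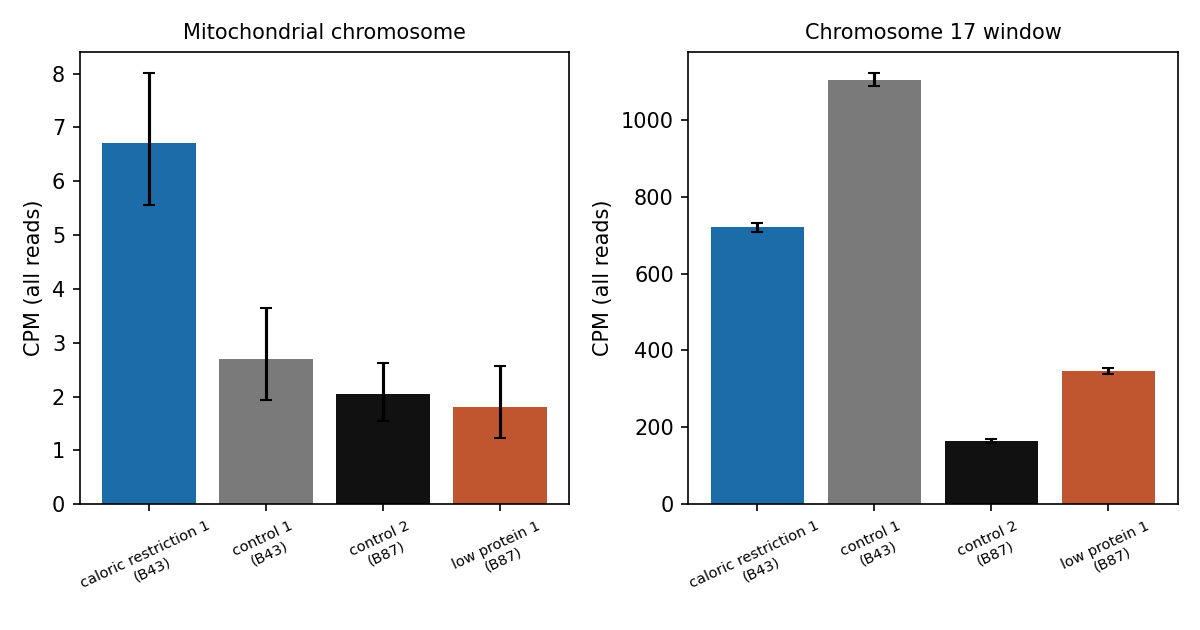
CPM over all reads (vertical axes, from 0) on the mitochondrial chromosome and in the chromosome 17 window from 39980001 to 39985000 for each library; error bars are exact Poisson 95% intervals and cover counting error only. Caloric restriction 1 has 6.70 CPM of mitochondrial reads against 1.80 to 2.69 in the others, and the chromosome 17 window ranges from 164 to 1105 CPM.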

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

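The tests in this part were chosen after the result was seen. The caloric restriction library held 121 mitochondrial reads, or 6.70 CPM (interval 5.56 to 8.01), above both controls, at 2.69 (1.93 to 3.65) and 2.04 (1.55 to 2.63) CPM; low protein 1 had 1.80 (1.23 to 2.56). The title code alone does not explain the excess, because caloric restriction 1 was 2.49-fold above control 1 of the same code (1.73 to 3.64). Copies of a few fragments do not account for it either, since 95.9% of its mitochondrial reads lay at distinct positions. Whether the caloric restriction diet or the handling of 1 sample is the cause cannot be told apart, because there is 1 library of that diet. Nor can more mitochondrial DNA be told from more methylation of it, since no input library was used. No group had the 4 libraries that a test for outlying samples needs.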

How the results depend on the processing

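No paired analysis was possible because the title code as a block, like leaving out either control, leaves 0 residual degrees of freedom. The naming rule fixes the direction of the 40 named windows against each control alone, and those 80 values have no test. Under the other alternatives 398 of 398 values kept their direction and 0 passed the threshold. The alternatives recount or rescale the same reads, and the named windows are the most extreme ones, so a kept direction is no separate support. Of 312851 windows, 32296 met the rule as higher and 31646 as lower for caloric restriction, and 32123 and 29690 for low protein. With limma, 0 windows were called for either diet under the alternatives other than the ones named here. All reads gave 1 call for low protein. In 50-kb windows, chosen after seeing the data, a minimum mean of 10 reads gave 17 calls for caloric restriction and 11 for low protein, and a minimum of 100 reads, chosen after those calls were seen, gave 0 and 0. At an unadjusted p under 0.05, cyclic loess gave 7126 and 5817 windows (smallest adjusted p 0.288 and 0.137).

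The percent of windows at least 2-fold apart moved with most settings, in the order caloric restriction 1 with control 1, with control 2 and with low protein 1, control 1 with control 2 and with low protein 1, and control 2 with low protein 1. With all reads it was 6.38, 7.32, 5.63, 15.7, 12.1 and 2.68. With a minimum mean of 30 reads it was 0.814, 1.68, 0.555, 6.36, 2.68 and 0.299. With median-ratio size factors it was 5.28, 6.10, 4.64, 13.4, 9.70 and 2.37. After loess on the mean log2 count it was 4.87, 4.49, 3.66, 7.87, 6.0 and 2.35. At 1.5-fold it was 22.5, 24.7, 20.04, 38.3, 32.7 and 14.6. In every one of these settings the controls were the most different pair and control 2 with low protein 1 the least. Why the percents moved with the setting was not tested.

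Without thinning, the percent for caloric restriction and for low protein against the control of the same code was 6.95 and 1.73. It was 7.47 and 1.94 with all reads, 1.36 and 0.162 with a minimum of 30 reads, 6.24 and 1.64 with median-ratio size factors, and 5.79 and 1.60 after loess. In windows chosen after seeing the data it was 4.06 and 0.644 at 10 kb and 0.0616 and 0.00212 at 50 kb. The correlation of these ratios stayed negative, at -0.0821 with all reads, -0.154 with a minimum of 30 reads, -0.0421 after loess, -0.126 at 10 kb and -0.416 at 50 kb. With a minimum of 30 reads, after loess, at 10 kb and at 50 kb, all chosen after seeing the data, r with the controls crossed was -0.476, -0.227, -0.549 and -0.832. Against the mean of the controls it was 0.248, 0.297, 0.173 and -0.0454, so that its sign turned at 50 kb; the cause was not tested. With all reads, the share of the top 10% of windows, the medians of chromosomes 3, 11 and X and the 1-Mb regions named on chromosomes 3, 4, 5, 7 and 17 moved by less than the SD of the controls. Regions with repeated reads moved by more: chromosome 2 from 98000001 to 99000000 went from 0.585 to 61.4 times the median region, and chromosome 11 from 3000001 to 4000000 from 2.93 to 4.60 times. Promoter, gene list and CpG density alternatives were not run. Depth limits single windows: named windows held 4 to 82 reads per library.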

Other observations

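The window with the most reads in all 4 libraries had them piled on few positions. Chromosome 2 from 98500001 to 98505000 held 16556 CPM over all reads in caloric restriction 1, 12100 in control 1, 13045 in control 2 and 10888 in low protein 1, at 310, 200, 364 and 195 reads per distinct position. After the window next to it, chromosome 9 from 35110001 to 35115000 held the most, with 3883, 2707, 3507 and 2921 CPM. Y chromosome reads were 569, 479, 951 and 866 CPM, lower in the libraries with code B43.

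In 50-kb windows, 1 axis held 87% of the variance between libraries and ordered them control 1, caloric restriction 1, low protein 1 and control 2, with loadings of 0.732, 0.178, -0.357 and -0.553. On that scale the ratios within a code had r = -0.416 (jackknife SE 0.0183). In 387718 windows of 5 kb, 2321 were at least 2-fold below both controls in caloric restriction 1 and 579 in low protein 1. Libraries drawn without a diet difference gave 5370 and 767 with the code difference kept, and 2084 and 1773 without it. Above both controls were 376 and 1087, against 222 and 1312 with the code difference and 565 and 589 without it. By the same rule control 1 lay below both diet libraries in 13059 windows and above them in 304, and control 2 in 1157 and 1735. With the code difference kept, the draws gave 5081 and 216 for control 1, and 879 and 1425 for control 2. Without it they gave 2044 and 557, and 2113 and 587. The 13059 windows lie far above the highest draw with the code difference (5183), so those draws did not describe control 1. They missed the other libraries as well. For control 2 the 1157 and 1735 windows lie above the highest draws (921 and 1507). In caloric restriction 1 the 376 windows lie above the highest draw (246), while its 2321 lie below the mean of the draws. Both counts of low protein 1 lie below the means. A departure from these draws is therefore no sign of a diet effect.

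The tests in the next paragraphs were chosen after the result was seen. The controls differed more than either diet library differed from the control of its code. Paternal diet does not explain a difference between the controls, since both had the same diet. The SD of their ratio beyond counting error, 0.528, restates that difference and is no separate test. With a trend with read level removed by loess, 7.87% of windows still differed at least 2-fold, against 3.03% from counting error. The trend that was removed is thus not the whole cause. The loess used the mean log2 count of the same libraries, which has counting error itself, so part of the trend may remain. The 3.03% was simulated without any trend, so the percents are not fully alike. A preparation batch that follows the title code is a candidate explanation, with a gap of 22.4 bp between the codes in the distance between strands against at most 14.8 bp within a code. It stays open, because caloric restriction 1 and low protein 1, of different codes, were about as close (SD 0.247) as caloric restriction 1 and control 1 (SD 0.244), and each code has 2 libraries.

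The chromosome 17 window from 39980001 to 39985000 set the controls further apart than either diet library and the control of its code. Diet alone does not explain the difference between the controls, since both had the same diet. That control 1 was 4.24-fold above control 2 in distinct positions is part of the pattern. It is no separate test of this window, which was singled out after its values were seen. A trend with read level stays open. In the 10% of windows with the most reads in the other libraries, outside the 50-kb window around it, the fold in distinct positions had a median of 1.33. That fold reached 4.42, with 4 of 43545 at or above 4.24. None is near the level of the chromosome 17 window (7802 distinct reads in those libraries against at most 3315). Distinct positions also ran short in the chromosome 17 window, with 54.1% of the possible ones used in control 1 and 23.1% in control 2. Its fold of 4.24 is therefore held down (6.75 with all reads), and a test against folds in distinct positions cannot decide. This test was redefined more than once after its values were seen: earlier versions with all reads, a median of 0.839 over 35 windows and then a highest fold of 2.06 over 34, spoke against the trend. Many copies of a sequence read at 1 place also stay open: reads per distinct position in caloric restriction 1, control 1, control 2 and low protein 1 were 2.51, 2.88, 1.81 and 1.81 times those of the library, above the 1.63, 1.91, 1.11 and 1.24 times from even scatter, but uneven enrichment would raise them too.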
